A study of Caenorhabditis elegans with 12 samples.

How the data were processed

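RNA was sequenced from whole Caenorhabditis elegans. 2 genotypes were compared: the wild-type strain N2 and unc-49(e407), which carries a mutation in the gene for the GABA-A receptor UNC-49. Per the labels, synchronised animals grew at 20 °C on Escherichia coli OP50, the standard laboratory food, to the L4 larval stage. They then spent 24 h at 25 °C on OP50 or on Pseudomonas aeruginosa PA14, a bacterium that kills the worm. Total RNA was extracted and 1 µg per sample went into a standard Illumina library; how RNA was selected is not stated. There are 12 libraries in 4 groups of 3, named by genotype, bacterium and replicate. The labels do not say whether the replicates were separate cultures, whether libraries with the same number were handled together, or which strand setting was used in counting.

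The deposited table gives FPKM, fragments per kilobase of gene model and mega (M) fragments, computed by the authors. Per the submitters' processing notes the reads were aligned with HISAT2 2.0.4 to the genome build WBcel235 and counted with HTSeq 0.9.1, and DESeq 1.18.0 is named for the authors' comparison of groups. The column sums range from 727361 to 909056 FPKM, so the values are not scaled to a common sum. The table lists 46842 genes. Of these, 46364 matched the Ensembl annotation of WBcel235 by identifier, 116 are transcripts that the authors' table adds to the annotation, and 362 others have no entry. Gene positions and types come from that annotation, and gene names from the gene name table or, where it has none, from the sequence name.

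Read numbers were recovered from the FPKM. Multiplied by the exon length of its gene, the FPKM of a library moves in equal steps, and the step size is the inverse of the depth. The depth obtained this way lies between 40.03 and 62.5 M reads per library. With this depth, the smallest gene length that gives whole read numbers in all libraries was searched for each gene. It was found for 13938 of the 13950 tested genes, within a tolerance of 0.05 reads plus a small share of the read number. With deliberately shifted depths such a length was found for 1 of 400 genes tried. At these depths 1 read in a gene of 1 kb corresponds to 0.0160 to 0.0250 FPKM. A value of 0 allows up to 3 reads, or 0.0480 to 0.0749 FPKM in such a gene, for counting error alone. Reads were not deduplicated with molecular identifiers, so counting error understates the error of low values.

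Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were kept, which left 13950, of which 12808 are protein coding and 198 have no annotation. One linear model with a mean per group was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with the moderated test of eBayes and an intensity trend (residual degrees of freedom 8, prior degrees of freedom 2.67). 5 contrasts were tested. These are PA14 against OP50 in each genotype, unc-49 against wild type on each bacterium, and the interaction, which is the exposure effect in unc-49 minus that in wild type. P values were adjusted by the Benjamini-Hochberg method over all tested genes, and 0.05 was the threshold. Log2 fold changes are differences of group means on the log2(FPKM + 1) scale, which makes changes of genes near 0 smaller than the ratio of their FPKM. Values are given as mean ± SD with n = 3 libraries.

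44 gene lists were written before the data were examined and tested with camera from limma with a preset correlation of 0.01 between genes. The same test with a correlation estimated for each list, and the rotation test fry, served as alternatives. The comparisons, the lists and the rule for naming genes were also set before the data were examined. The rule names unc-49 and 17 further genes whatever their result. It adds for each comparison of 2 groups the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 5 FPKM. From each list it takes up to 4 members past the threshold with the largest change. In the Results, genes named outside this rule are said to be so. The sections after them also name genes outside it without saying so each time. Reads shared between similar genes, as among collagens or C-type lectins, were assigned by the authors' pipeline and could not be separated again.

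The overlap of PA14 against OP50 in wild type with unc-49 against wild type on OP50 was compared with 100 simulated sets of unchanged groups, since both use the wild-type OP50 libraries. Alternatives were other pseudocounts (0.1 and 5), no filter or a mean of at least 5 FPKM, 3 other scalings between libraries, no intensity trend, library weights, a replicate block, only the libraries compared, a fold-change minimum, and leaving out each library in turn. A robust prior and limma's voom on the recovered reads were added after seeing the data. So were the exposure effect averaged over genotypes and the genotype effect averaged over bacteria. The other programs were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

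The procedure was tested on simulated counts with the depths and spread of these libraries, in which 100 genes changed 2-fold and 100 changed 4-fold among 13938. For PA14 against OP50 in wild type it recovered 45 and 86 of them with 7 false calls. In unc-49 it recovered 41 and 86 with 10 false calls. For unc-49 against wild type it recovered 48 and 82 with 7 false calls on OP50, and 47 and 81 with 6 false calls on PA14. For the interaction it recovered 14 and 52 with 8 false calls. None of the recovered genes had the wrong direction. The changed genes were not drawn from the lowest expressed genes, so recovery there is not known. Genes were simulated independently and without a batch shared between libraries, so the false calls in the real libraries may differ. No library was left out, and no read-level reanalysis was possible.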

Results

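The series measured RNA of whole worms, given as FPKM per gene, in wild-type and unc-49(e407) animals that had spent 24 h on OP50 or on PA14 from the L4 stage. Its stated aim was to find genes regulated by UNC-49 in uninfected and infected animals. Each of the 4 groups had 3 libraries. Depth in mega (M) reads was 42.5, 40.03 and 57.2 for wild type on OP50, 49.9, 45.8 and 51.6 for wild type on PA14, 48.3, 46.1 and 62.5 for unc-49 on OP50, and 50.2, 53.7 and 53.3 for unc-49 on PA14. Between 12340 and 13418 genes reached 1 FPKM in a library. The first principal component of the log2 values held 43.4% of the variance and separated all 6 PA14 libraries from all 6 OP50 libraries. The genotypes were not separated by it, and the second component, with 13.5%, ordered the libraries by replicate number within every group. Its values were 9.63 to 38.66 for replicates 2, -3.3 to 8.66 for replicates 1 and -26.66 to -9.55 for replicates 3.

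**Figure D1:**
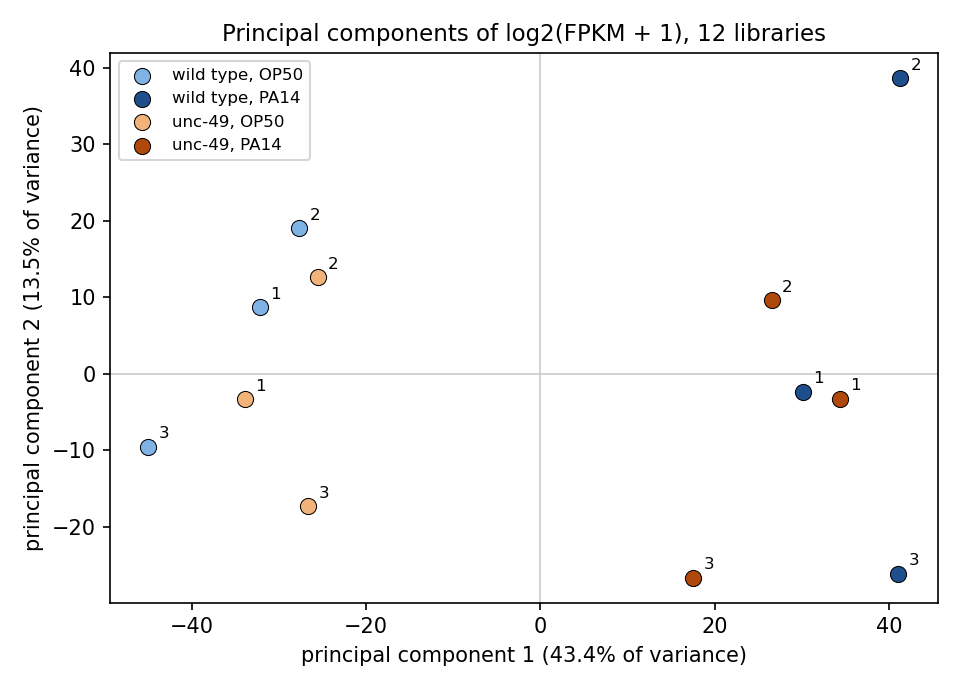
Each point is 1 library, placed by its first principal component (x axis, 43.4% of variance) and second principal component (y axis, 13.5% of variance) of log2(FPKM + 1), coloured by group and numbered by replicate. PA14 libraries lie at positive values of the first component, from 17.53 to 41.26, and OP50 libraries at negative values, from -45.02 to -25.57.

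Transcripts of the mutated gene were present in all groups. unc-49 (WBGene00006784) lies on chromosome III between 10520762 and 10532705 in WBcel235. It measured 9.38 ± 0.134 FPKM in wild type on OP50, 8.84 ± 1.27 in wild type on PA14, 8.13 ± 1.19 in unc-49 on OP50 and 8.72 ± 1.45 in unc-49 on PA14. None of the 4 comparisons of 2 groups passed the threshold for it with limma, with adjusted p from 0.768 to 0.994.

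The first comparison asks how wild-type animals respond to PA14. PA14 took the place of OP50, their food until then, so infection and the change of food cannot be told apart in either genotype. cld-1, B0024.4, dod-21 and dod-24 rose, as did the infection response genes irg-1, irg-2, irg-3 and irg-5. Enzymes of the propionate shunt and of the methionine cycle fell, and so did the metallothionein mtl-2 and the cathepsin B type proteases cpr-1 and cpr-5. Immune effectors that depend on the p38 kinase PMK-1 and members of the intracellular pathogen response ranked higher as lists. Cuticle collagens, moulting genes and nuclear genes of the respiratory chain ranked lower. None of these list calls held with an estimated correlation (adjusted p from 0.342 to 0.355).

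Of 13950 genes tested with limma, 1432 passed the threshold, 674 higher and 758 lower on PA14. 739 of them changed at least 2-fold. In 29.3% of all genes the 3 libraries of one group lay above all 3 of the other, where chance gives 10%. The count fell to 595 without replicate 3 of wild type on OP50, to 751 without replicate 1 of that group and to 890 without replicate 3 of wild type on PA14. Whether more genes rose or fell depended on scaling and on single libraries. Rescaling to a common sum gave 761 higher and 650 lower. The count was 740 higher and 372 lower without replicate 2 of wild type on PA14, and 524 and 969 without replicate 1. On OP50 it was 388 and 363, 671 and 458, and 361 and 234 without replicate 1, 2 or 3.

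Among the largest rises, cld-1 (WBGene00007872, chromosome IV) went from 0.146 ± 0.126 to 158 ± 31 FPKM (log2 fold change 7.10, adjusted p = 1.05e-07). The gene B0024.4 (WBGene00007097, chromosome V) went from 3.19 ± 3.54 to 458 ± 178 FPKM (log2 fold change 7.04, adjusted p = 1.84e-04). dod-21, from 0.409 to 137 FPKM, irg-5 and Y47H9C.1 followed with log2 fold changes of 6.66, 5.05 and 4.97. irg-5 (WBGene00009429) rose from 8.52 ± 3.82 to 318 ± 148 FPKM and irg-3 (WBGene00018760) from 20.8 ± 3.77 to 358 ± 61.4 FPKM. The other genes with the largest rises were the claudin-like genes clc-12 and clc-19, dod-24, C50F7.5 and C49G7.12, with log2 fold changes from 4.48 to 4.63. The glutathione transferase gst-38 rose by 4.30, the protease gene cpr-3 by 4.01 and the lysozyme lys-2 by 2.88 on the log2 scale. Among the falls, the acyl-CoA dehydrogenase acdh-1 (WBGene00016943, chromosome I) dropped from 651 ± 151 to 3.23 ± 2.38 FPKM (log2 fold change -7.39, adjusted p = 1.91e-04). mtl-2, cpr-1 and acdh-2 had log2 fold changes of -5.31, -5.10 and -4.64. Their OP50 libraries differed widely, with SDs of 376, 464 and 47.1 FPKM. The calls of mtl-2 and cpr-1 ended with voom on the recovered reads. The peroxisomal transporter pmp-5 fell from 32.3 ± 2.64 to 2.27 ± 0.666 FPKM and the S-adenosylmethionine synthetase sams-1 from 114 ± 3.64 to 22 ± 5.26 FPKM.

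**Figure D2:**
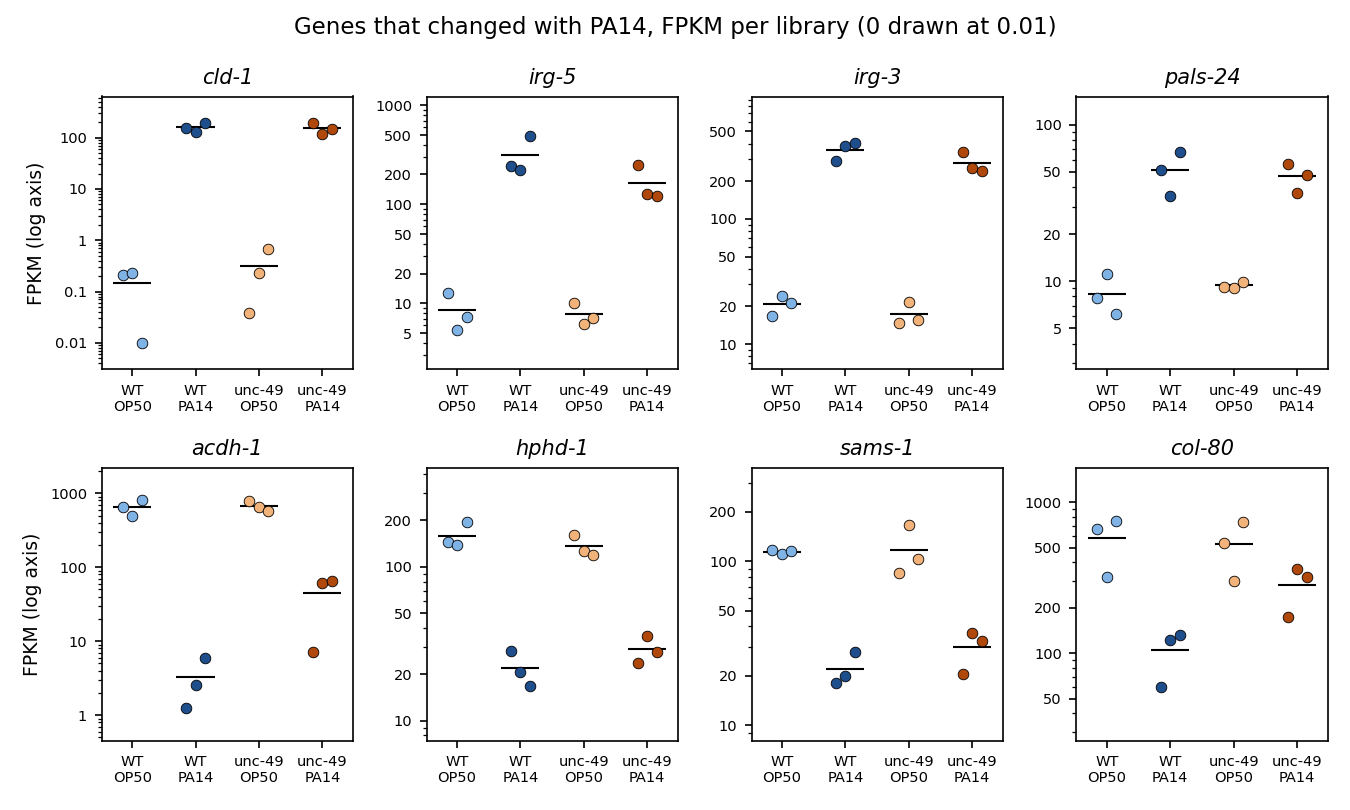
FPKM per library on a log axis for 8 genes that changed with PA14 in wild type, by group, with a point per library and a line at the group mean. A value of 0, as in 1 wild-type OP50 library for cld-1, is drawn at 0.01; cld-1, irg-5, irg-3 and pals-24 were higher and acdh-1, hphd-1 and sams-1 lower in every PA14 library of both genotypes, and col-80 lower in those of wild type alone.

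Several immune lists ranked higher on PA14, but not all. Antimicrobial peptides and lysozymes had negative medians, -0.27 and -0.06. For effectors that depend on the p38 kinase PMK-1, 10 of 14 measured members passed the threshold and 11 when adjusted over the list alone (median log2 fold change 2.58, camera adjusted p = 1.74e-10, adjusted p = 0.342 with an estimated correlation). The members irg-5, dod-24, clec-4 and lys-2 changed most. For genes lowered when the factor DAF-16 is active, 5 of 9 measured members passed the threshold and 7 when adjusted over the list alone (median log2 fold change 1.47, camera adjusted p = 2.52e-08, adjusted p = 0.12 with an estimated correlation). They include dod-21, dod-19, dod-17 and also dod-24, which the p38 list holds too. For response genes independent of p38, 6 of 9 measured members passed the threshold and 6 when adjusted over the list alone (median log2 fold change 0.98, camera adjusted p = 4.26e-06, adjusted p = 0.342 with an estimated correlation). irg-1 rose from 2.09 to 77 FPKM and irg-2 from 1.54 to 44.6 FPKM. For the intracellular pathogen response, 9 of 19 measured members passed the threshold and 9 when adjusted over the list alone (median log2 fold change 0.46, camera adjusted p = 3.89e-06, adjusted p = 0.355 with an estimated correlation). 2 members fell when adjusted over the list alone. pals-24 and pals-23 rose most in it, by 2.46 and 2.27 on the log2 scale, with skr-3 and skr-4. Of 267 F-box and MATH-BTB genes, 35 rose and 1 fell, and 43 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0445, adjusted p = 0.899 with an estimated correlation). Their median of -0.06 was below 0 while their mean of 0.08 and camera's direction were above 0, and the median's sign changed with quantile normalization. C-type lectins moved both ways, with 17 of 102 higher and 10 lower, and 23 higher and 17 lower when adjusted over the list alone (camera adjusted p = 0.071).

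Several metabolic and epidermal lists ranked lower. For the propionate shunt, 5 of 5 measured members passed the threshold and 5 when adjusted over the list alone (median log2 fold change -1.62, camera adjusted p = 9.61e-08, adjusted p = 0.105 with an estimated correlation). Besides acdh-1, hphd-1 fell from 159 to 21.9 FPKM and ech-6 from 359.9 to 116 FPKM. For the methionine cycle, 7 of 11 measured members passed the threshold and 9 when adjusted over the list alone (median log2 fold change -0.41, camera adjusted p = 9.35e-05, adjusted p = 0.342 with an estimated correlation). For cuticle collagens, 25 of 94 measured members passed the threshold and 40 when adjusted over the list alone (median log2 fold change -0.90, camera adjusted p = 2.57e-12, adjusted p = 0.345 with an estimated correlation). col-93, col-80, col-94 and col-179 fell most, with log2 fold changes from -2.50 to -2.31. For hedgehog-related and moulting genes, 6 of 33 measured members passed the threshold and 16 when adjusted over the list alone (median log2 fold change -0.90, camera adjusted p = 5.59e-07, adjusted p = 0.342 with an estimated correlation). For nuclear genes of oxidative phosphorylation, 10 of 47 measured members passed the threshold and 19 when adjusted over the list alone (median log2 fold change -0.29, camera adjusted p = 2.80e-09, adjusted p = 0.355 with an estimated correlation). All 47 of them had a negative fold change. Of 50 genes of fatty acid activation and oxidation 6 fell and 2 rose, and 7 fell and 2 rose when adjusted over the list alone, and the list did not pass (median -0.03, camera adjusted p = 0.547). Cytosolic ribosomal proteins and body wall muscle genes were the other 2 lower lists. All 81 ribosomal genes had a negative fold change, and 0 of 81 measured members passed the threshold and 0 when adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 4.55e-05, adjusted p = 0.899 with an estimated correlation). The ribosomal median was -0.092 with quantile normalization and -0.162 to -0.166 with the other scalings and voom. For body wall muscle, 2 of 24 measured members passed the threshold and 2 when adjusted over the list alone (median log2 fold change -0.23, camera adjusted p = 0.0401, adjusted p = 0.899 with an estimated correlation). Of the higher lists, sperm markers had a median of 0.25 (camera adjusted p = 0.031) and oocyte and embryo markers of 0.16 (camera adjusted p = 0.00232). Both held 0 members past the threshold over all genes or when adjusted over the list alone, and adjusted p = 0.899 with an estimated correlation for each. Of 16 intestinal genes 5 rose and 2 fell, and 6 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.0377, adjusted p = 0.852 with an estimated correlation). Their median of 0.18 and camera's direction were above 0 while their mean of -0.23 was below. In all, 19 of 44 lists passed with camera, 12 higher and 7 lower. 0 of these held with an estimated correlation, and 9 lists passed with fry.

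The second comparison asks the same of unc-49 animals. cld-1, dod-21, B0024.4 and Y47H9C.1 had the largest rises, and irg-5 and irg-3 were among the 10 largest. The propionate shunt and pmp-5 fell again, and acdh-1 had the largest fall again. Collagens and respiratory chain genes had negative medians, -0.42 and -0.18, and neither list held with an estimated correlation (adjusted p = 0.612 and 0.573).

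With limma 474 genes passed, 354 higher and 120 lower on PA14, of which 348 changed at least 2-fold. Groups did not overlap for 21.1% of genes, where chance gives 10%. The count was 255, 311 and 280 without replicate 1, 2 or 3 on OP50, and 239 and 235 without replicate 1 or 3 on PA14.

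cld-1 rose from 0.316 ± 0.328 to 153 ± 39.1 FPKM (log2 fold change 6.87, adjusted p = 1.52e-07). dod-21 and B0024.4 rose by 6.46 and 5.80 on the log2 scale. irg-5 rose from 7.85 ± 1.99 to 165 ± 71.8 FPKM and irg-3 from 17.4 ± 3.73 to 280.3 ± 52.8 FPKM. acdh-1 fell from 664 ± 103 to 44.8 ± 32.8 FPKM (log2 fold change -4.35, adjusted p = 0.00615). pmp-5 and T13F3.6 fell, with log2 fold changes of -2.87 and -2.58. mtl-2, acdh-2, F42A10.7 and T16G1.7 were also among the 10 largest falls, but each lost its call without at least 3 of the 6 libraries in turn. With a replicate block F42A10.7 did not pass (adjusted p = 0.0514). The same held for irg-1 without 5 of them and for clc-19 without 3.

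For the p38-dependent effectors, 6 of 14 measured members passed the threshold and 10 when adjusted over the list alone (median log2 fold change 1.88, camera adjusted p = 5.31e-12, adjusted p = 0.179 with an estimated correlation). For the genes lowered with DAF-16 active, 4 of 9 measured members passed the threshold and 5 when adjusted over the list alone (median log2 fold change 1.37, camera adjusted p = 1.61e-09, adjusted p = 0.0788 with an estimated correlation). For the response genes independent of p38, 6 of 9 measured members passed the threshold and 6 when adjusted over the list alone (median log2 fold change 0.94, camera adjusted p = 2.31e-07, adjusted p = 0.222 with an estimated correlation). For the propionate shunt, 5 of 5 measured members passed the threshold and 5 when adjusted over the list alone (median log2 fold change -1.17, camera adjusted p = 1.61e-09, adjusted p = 0.0496 with an estimated correlation). It was the 1 list of any comparison that held with an estimated correlation. For the methionine cycle, 6 of 11 measured members passed the threshold and 9 when adjusted over the list alone (median log2 fold change -0.43, camera adjusted p = 2.97e-09, adjusted p = 0.116 with an estimated correlation). Among 94 cuticle collagens 3 fell, and 2 when adjusted over the list alone, with a median of -0.42 (camera adjusted p = 2.26e-06, adjusted p = 0.612 with an estimated correlation). Of 47 genes of oxidative phosphorylation 0 passed with limma over all genes or when adjusted over the list alone (camera adjusted p = 1.25e-08, adjusted p = 0.573 with an estimated correlation, fry adjusted p = 0.112). With the replicate block gas-1, ucr-2.2 and sdha-1 of this list passed (adjusted p = 0.0268, 0.0344 and 0.0497). In all, 15 of 44 lists passed with camera and 5 with fry.

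Most genes called in unc-49 were also called in wild type, while most of those called in wild type were not called in unc-49. Of the genes higher on PA14 in unc-49, 344 of 354 were also higher in wild type, and of the genes lower, 116 of 120 were also lower. 0 genes passed in opposite directions. The log2 fold changes correlated across the 13950 genes with a Pearson r of 0.872 and a Spearman rho of 0.789, although genes are not independent replicates. Over the 1432 genes called in wild type, the median change was 1.03 in wild type and 0.69 in unc-49 in the same direction. Those genes were chosen by their size in wild type, so a smaller median in unc-49 follows in part from that choice.

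**Figure D3:**
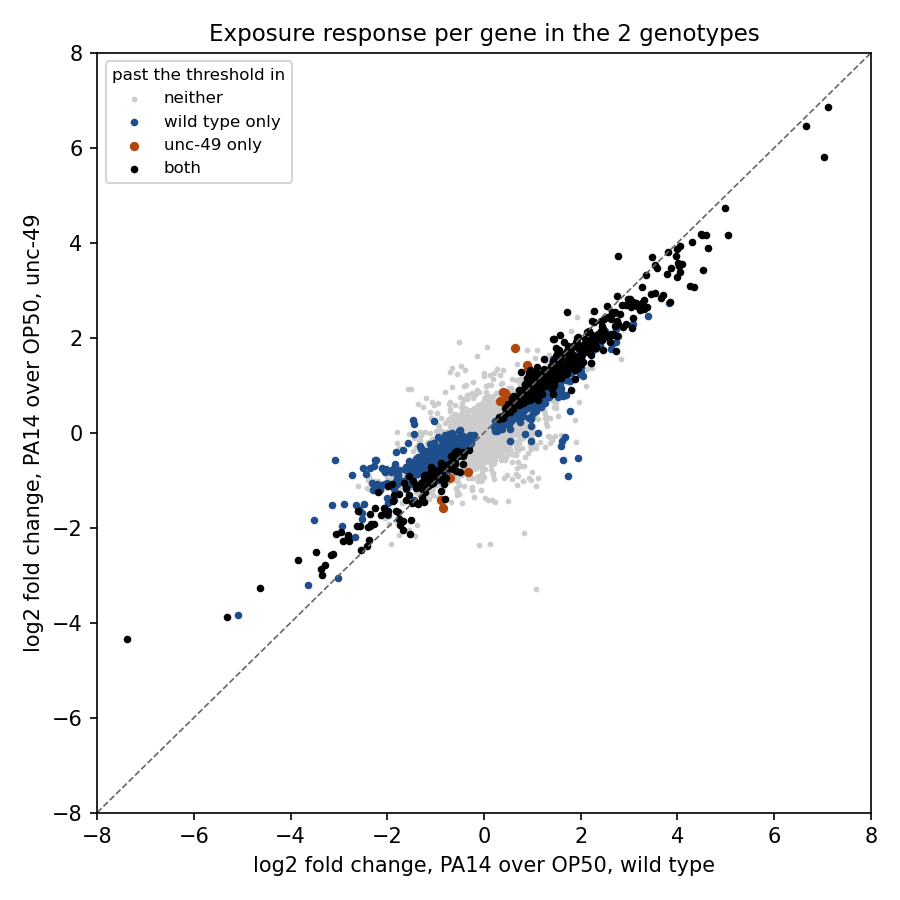
Each point is 1 gene, with its log2 fold change of PA14 over OP50 in wild type on the x axis and in unc-49 on the y axis, coloured by the genotype in which it passed the threshold; the dashed line marks equal change. Across genes r was 0.872, and acdh-1 lies at the far left with -7.39 and -4.35.

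The third comparison asks which genes differ between unc-49 and wild type on OP50. The DNA repair gene ung-1, the arrestin-domain gene arrd-13 and the non-coding RNA F39E9.25 were lower in unc-49. Mostly uncharacterised genes were higher, among them C08F11.7, C08F11.6, C44B12.6, C07G1.7, C38D9.2 and the neuropeptide receptor gene pdfr-1. The p38-dependent effectors, cuticle collagens and GABA transmission genes held 0 members past the threshold, over all genes or when adjusted over the list alone.

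With limma 22 genes passed, 18 higher and 4 lower in unc-49, and 19 of them differed at least 2-fold. Groups did not overlap for 14.2% of genes, where chance gives 10%. The count was 11, 8 and 10 without replicate 1, 2 or 3 of wild type, and 10 and 7 without replicate 2 or 3 of unc-49.

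ung-1 (WBGene00013241, chromosome III, 11971467 to 11974096) measured 109 ± 7.08 FPKM in wild type and 6.7 ± 0.749 in unc-49 (log2 fold change -3.83, adjusted p = 4.29e-08). arrd-13 (WBGene00011054, chromosome II) measured 67.2 ± 2.04 and 32.9 ± 2.3 FPKM (log2 fold change -1.01, adjusted p = 1.99e-04). F39E9.25 (WBGene00195025, chromosome II, 3309254 to 3309274), annotated as a short non-coding RNA, measured 42.2 ± 10.2 FPKM in wild type and is listed at 0 in all 3 unc-49 libraries. Over so short a stretch 1 read is worth far more FPKM than in a gene of 1 kb. The fourth lower gene, B0511.11, chosen for mention after its values were seen, measured 4.7 and 1.28 FPKM. Of the higher genes, C08F11.7 (WBGene00007454, chromosome IV) went from 0.781 ± 0.437 to 9.37 ± 1.17 FPKM (log2 fold change 2.57, adjusted p = 2.41e-04) and C44B12.6 from 3.1 ± 0.521 to 10.5 ± 1.17 FPKM (log2 fold change 1.49, adjusted p = 0.00165). The neighbouring pseudogene C08F11.6 rose from 2.09 to 13.2 FPKM and the transthyretin-like gene ttr-39 from 3.62 to 12.9 FPKM. C07G1.7, from 0.0338 to 21.5 ± 13.2 FPKM, and ZK177.9, from 0.0403 to 7.18 ± 5.49 FPKM, had the highest fold changes, 4.29 and 2.78. Both overlap another gene on the opposite strand, so the strand that gave their reads is not known. The calls of C07G1.7, ZK177.9, C38D9.2, T02G5.11, ttr-39, Y43F8B.1 and pdfr-1 each ended without at least 3 of the 6 libraries in turn, and that of C08F11.6 without replicate 3 of unc-49.

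6 lists passed with camera, all higher in unc-49, and 0 with an estimated correlation or with fry. They are body wall muscle (median 0.23, adjusted p = 0.00358), neuropeptides (median 0.15), cytosolic heat shock (median 0.74), oocyte and embryo markers (median 0.07), the p38-dependent effectors (median 0.46) and antimicrobial peptides (median 0.22). With an estimated correlation, adjusted p = 0.951 for each. 0 members of these 6 lists passed over all genes or when adjusted over the list alone. The list count was 14 without replicate 2 of wild type and 10 without replicate 3 of unc-49.

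The fourth comparison asks which genes differ between the genotypes on PA14. ung-1, arrd-13 and F39E9.25 were again lower in unc-49, and C08F11.7, C44B12.6, C40A11.8 and C07G1.7 higher, as on OP50. col-142, the cuticlin-like gene cutl-10 and C34C12.12 were higher as well. Cuticle collagens had a median of 0.66, with 1 of 94 past the threshold, and the list call did not hold with an estimated correlation (adjusted p = 0.804) or with fry (adjusted p = 0.324).

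With limma, in a model that treats the libraries as unpaired, 47 genes passed, 41 higher and 6 lower in unc-49, and 40 of them differed at least 2-fold. With a replicate block 133 passed, so the count depends on whether libraries with the same number share a batch. Groups did not overlap for 9.3% of genes, where chance gives 10%. The count was 24 without replicate 1 of wild type, and 18 and 15 without replicate 2 or 3 of unc-49.

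ung-1 measured 93.2 ± 10.2 FPKM in wild type and 6.36 ± 0.648 in unc-49 (log2 fold change -3.68, adjusted p = 6.69e-08). arrd-13 measured 70.8 ± 5.5 and 35.4 ± 0.248 FPKM (log2 fold change -0.98, adjusted p = 2.81e-04). F39E9.25 measured 58.4 ± 18.4 FPKM in wild type and 0.625 ± 1.08 in unc-49. Its neighbour F39E9.17 (3309988 to 3310006) measured 14.1 ± 9.39 FPKM in wild type and is listed at 0 in unc-49. Both span so few bases that their FPKM rest on far fewer reads than the same FPKM in a gene of 1 kb. C08F11.7 rose from 0.866 ± 0.261 to 9.05 ± 0.394 FPKM (log2 fold change 2.44, adjusted p = 4.02e-04), C44B12.6 by 1.70 and C40A11.8 by 1.98 on the log2 scale. cutl-10 (WBGene00013180, chromosome I) measured 1.54 ± 0.354 and 7.1 ± 0.621 FPKM (log2 fold change 1.68, adjusted p = 0.00715), and col-142 9.95 ± 2.34 and 36.3 ± 8.9 FPKM (log2 fold change 1.76, adjusted p = 0.0285). The call of cutl-10 ended without replicate 3 of unc-49 on PA14, as did that of C07G1.7. The calls of C34C12.12 and F39E9.17 ended without replicate 2 or 3 of unc-49, and that of col-142 without 4 of the 6 libraries in turn. The superoxide dismutase sod-3 was higher in all 3 unc-49 libraries than in all 3 wild-type libraries on each bacterium. It went from 3.18 to 10.6 FPKM on OP50 (adjusted p = 0.159) and from 3.9 to 13.6 FPKM on PA14 (adjusted p = 0.0701), neither past the threshold in the unpaired model. With the block it passed on both (adjusted p = 0.0324 and 0.0156).

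**Figure D4:**
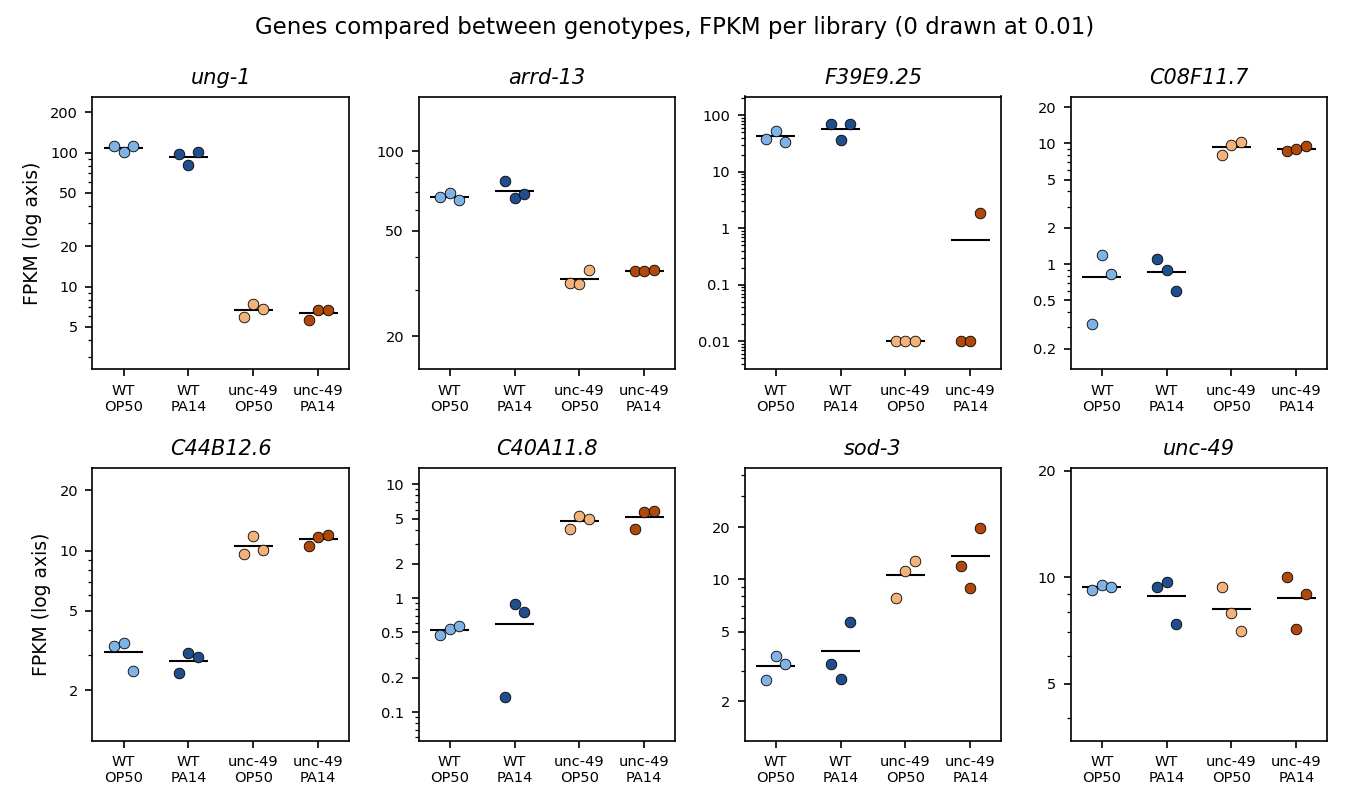
FPKM per library on a log axis for 8 genes compared between genotypes, by group, with a point per library and a line at the group mean; values of 0 are drawn at 0.01. ung-1 and arrd-13 were lower and C08F11.7, C44B12.6, C40A11.8 and sod-3 higher in every unc-49 library, while unc-49 overlapped.

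14 of 44 lists passed with camera, 7 higher and 7 lower in unc-49. 0 held with an estimated correlation, and 1, the mitochondrial unfolded protein response, passed with fry. Of 94 cuticle collagens 88 were higher in unc-49, 1 of them past the threshold over all genes and 1 when adjusted over the list alone (camera adjusted p = 3.15e-14, adjusted p = 0.804 with an estimated correlation). For hedgehog-related and moulting genes the median was 0.38 (camera adjusted p = 6.21e-05, adjusted p = 0.804 with an estimated correlation), with 0 members past the threshold in either way of adjusting. Of 24 body wall muscle genes 0 passed over all genes and 3 rose when adjusted over the list alone (camera adjusted p = 1.73e-04, adjusted p = 0.804 with an estimated correlation). Of 11 genes of the mitochondrial unfolded protein response, 0 passed over all genes and 2 rose when adjusted over the list alone (camera adjusted p = 0.00977, adjusted p = 0.573 with an estimated correlation). Its member hsp-6 was higher by 0.65 on the log2 scale, with all 3 unc-49 libraries above all 3 of wild type, and did not pass in the unpaired model (adjusted p = 0.125), while it passed with the replicate block (adjusted p = 0.00943). The 7 lower lists were zygotic embryo markers (median -0.25, camera adjusted p = 1.73e-04), F-box and MATH-BTB genes (-0.12, 5.59e-04), histones (-0.15, 6.92e-04), autophagy (-0.11, 0.00236), sperm markers (-0.17, 0.00754), the endoplasmic reticulum unfolded protein response (-0.06, 0.00754) and insulin signalling (-0.06, 0.0371). 0 of their members were lower past the threshold over all genes or when adjusted over the list alone, where 2 of 267 F-box and MATH-BTB genes were higher in both ways and 1 of 65 sperm markers in the list alone. With an estimated correlation, adjusted p = 0.804 for insulin signalling and the unfolded protein response and adjusted p = 0.919 for the other 5. The other higher lists were oxidative phosphorylation (median 0.11, camera adjusted p = 0.00236, adjusted p = 0.919 with an estimated correlation), the propionate shunt (0.41, 0.0207, 0.804) and antimicrobial peptides (0.31, 0.0108, 0.919). 0 of their members passed over all genes, and 1 of 5 in the propionate shunt when adjusted over the list alone. The median of oxidative phosphorylation was 0.043 to 0.07 with the other scalings and voom.

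**Figure D5:**
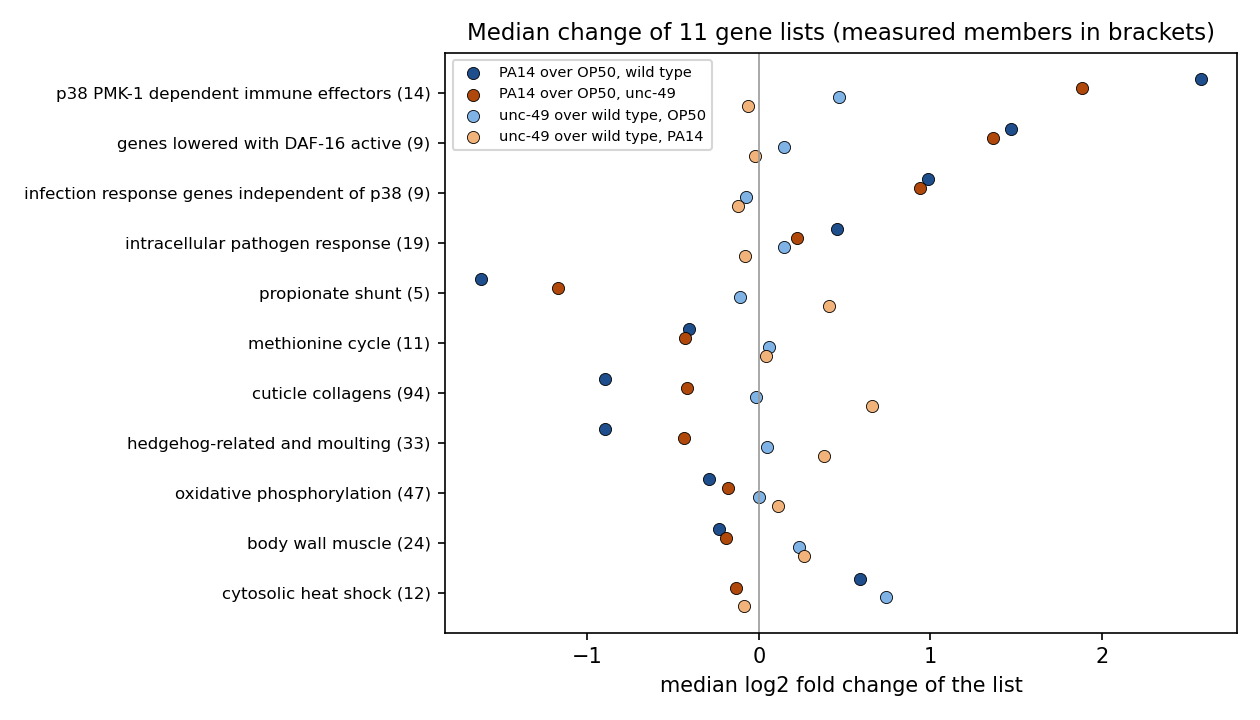
Median log2 fold change (x axis) of 11 gene lists in the 4 comparisons of 2 groups, with the number of measured members in brackets. The p38-dependent effectors lie at 2.58 in wild type and 1.88 in unc-49 for PA14 over OP50, and cuticle collagens at -0.90 and -0.42.

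Most of the genes called between genotypes on OP50 were also called on PA14, where more genes passed. Of the 18 genes higher in unc-49 on OP50, 16 were also higher on PA14, and all 4 lower genes were lower on both. Across all genes the fold changes correlated with a Pearson r of 0.467 and a Spearman rho of 0.411. 0 of the 22 genes passed for PA14 against OP50 in wild type, where independent lists share 1.09 in the same direction and 1.17 in opposite directions. Both comparisons use the wild-type OP50 libraries, which alone gave a covariance of 0.0341 across genes in simulations (0.0315 to 0.0370). The covariance observed was 0.0493, or 0.0152 above it. The Pearson r went the other way, 0.278 against a simulated 0.499 (0.469 to 0.533), as did the share of genes with the same sign, 57.6% against 66.7% (65.7% to 68.1%). The simulated groups did not respond to PA14, while 1432 genes passed in wild type, and such a response alone changes r and the share. Simulated genes also varied independently of each other, which makes the ranges too narrow. The simulation therefore cannot decide whether the 2 comparisons are related.

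The last comparison asks whether the response to PA14 differs between the genotypes. 0 genes passed the threshold with limma, at the smallest adjusted p of 1, while 163 had an unadjusted p under 0.05. 0 passed with voom on the recovered reads or with library weights, and 2 passed when no filter on low values was used. These were the 21-base RNAs 21ur-6722 and 21ur-14609, named after their values were seen, each with reads in 3 of 12 libraries. acdh-1 fell by 7.39 on the log2 scale in wild type and by 4.35 in unc-49, a difference of 3.04 that did not pass (adjusted p = 1). 13 lists passed with camera, 0 with an estimated correlation and 0 with fry. For cuticle collagens the median difference was 0.49, with 86 of 94 above 0 (camera adjusted p = 4.85e-13, adjusted p = 0.728 with an estimated correlation). For hedgehog-related and moulting genes it was 0.44, with 33 of 33 above 0 (camera adjusted p = 1.66e-06, adjusted p = 0.728 with an estimated correlation). For the p38-dependent effectors it was -0.40, with 12 of 14 below 0 (camera adjusted p = 0.00341, adjusted p = 0.827 with an estimated correlation). For cytosolic heat shock genes it was -0.96 (camera adjusted p = 4.95e-05, adjusted p = 0.827 with an estimated correlation). 0 members of these lists passed over all genes or when adjusted over the list alone.

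Of the 18 genes named in advance, 14 passed in none of the 4 comparisons of 2 groups. Besides unc-49, sod-3 and hsp-6 these were the immune genes irg-4 and lys-7, the metallothionein mtl-1, the glutathione transferase gst-4, the chaperone hsp-4, cysl-2, clec-60, ins-7, vit-2, daf-16 and pmk-1. With the replicate block sod-3 and hsp-6 passed as given above, and daf-16 passed for PA14 in unc-49 (log2 fold change 0.28, adjusted p = 0.0355). sysm-1, a p38-dependent effector, rose in wild type from 317 ± 84.9 to 931 ± 396 FPKM (log2 fold change 1.5, adjusted p = 0.0362), a call that ended without 5 of the 6 libraries in turn. In unc-49 it went from 587 ± 345 to 1172 ± 266 FPKM (adjusted p = 0.208). pmk-1 measured 19.1 and 15.1 FPKM in wild type, and daf-16 60.7 and 68.6 FPKM. gst-4 was higher in all 3 unc-49 libraries on PA14 than in all 3 of wild type, 25.3 against 9.74 FPKM, without passing (adjusted p = 0.799).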

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

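The count of splits, the comparison of exposure sizes and its scaling test were chosen after the results were seen; the test without cuticle and moulting genes was written before its result was seen.

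The interaction test singled out 13 gene lists, which passed with camera at the preset correlation. The median difference, unc-49 minus wild type, was 0.495 for cuticle collagens, 0.442 for hedgehog-related and moulting genes, 0.448 for the propionate shunt, 0.153 for cytochrome P450 genes and 0.113 for oxidative phosphorylation. It was -0.96 for cytosolic heat shock genes, -0.401 for p38-dependent immune effectors, -0.166 for histones, -0.162 for the intracellular pathogen response and -0.146 for insulin-like peptides. It was -0.138 for zygotic embryo markers, -0.087 for oocyte and embryo markers and -0.064 for F-box and MATH-BTB genes. All 13 medians kept their sign with 3 other scalings and with voom, and their sizes moved. With voom they were -2.014 for heat shock genes, 0.844 for collagens, -0.318 for histones and -0.199 for F-box and MATH-BTB genes. Voom also gave -0.272 for insulin-like peptides, -0.265 for zygotic embryo markers and -0.147 for oocyte and embryo markers. Median-ratio scaling gave 0.054 for oxidative phosphorylation. 0 of the 13 lists held with an estimated correlation (adjusted p from 0.54 to 0.827) or with fry (adjusted p = 0.997). The count was 20 without replicate 2 of wild type on OP50. 57 of 100 regroupings of the libraries gave at least 13 lists, the highest other 23, so chance is not excluded.

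The cuticlin-like gene cutl-10 was singled out because its groups did not overlap in either genotype. It was lower on PA14 than on OP50 in wild type and higher in unc-49. It passed in neither of these exposure comparisons with limma (adjusted p = 0.0844 and 0.507). Its interaction was 0.98 on the log2 scale and did not pass (adjusted p = 1). Of the 13950 tested genes 6, or 0.04%, lay in opposite directions in this way. 0 genes passed the interaction with limma, and 163 had an unadjusted p under 0.05. A count of 0 is reached by all 100 regroupings whatever the data, so they decide nothing about it; the highest other gave 201. That regrouping set replicates 1 and 2 of wild type and 2 of unc-49 against the other 3 OP50 libraries. On PA14 it set replicate 3 of wild type and 2 and 3 of unc-49 against the rest. So many calls point to a structure of the libraries outside their groups.

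For the comparisons of 2 groups, 10 splits of 6 libraries are too few for a share under 0.05. The real count and the highest of the other splits were 1432 and 1 for PA14 against OP50 in wild type and 474 and 0 in unc-49. They were 22 and 2 for unc-49 against wild type on OP50, and 47 and 6 on PA14. In each of these 1 of 10 splits, the real one, gave as many genes. For gene lists they were 19 and 25 (3 of 10 splits as large), 15 and 19 (7 of 10), 6 and 19 (10 of 10) and 14 and 16 (3 of 10).

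The exposure effects were smaller in unc-49. Averaged over genotypes, 2531 genes passed for PA14 against OP50, 1108 higher and 1423 lower. Their median effect was 0.83 on the log2 scale in wild type and 0.59 in unc-49, and 84.1% had the smaller effect in unc-49. The mean difference toward 0 was -0.253, and -0.161 for genes that rose and -0.325 for genes that fell. It ranged from -0.309 to -0.197 when each library was left out in turn. 3 of 100 random regroupings of the genotype labels within each bacterium, the real one included, had a mean as large, and the largest size among the others was 0.291. The draw was changed once after a first result was seen. Among all 200 possible regroupings 8 were as large, so the share does not rest on the draw. The 2531 genes were chosen once, by a test that uses the spread within the real groups. Such a choice favours genes that vary little within those groups, which can make the mean smaller in the other regroupings. The shares therefore cannot decide whether chance accounts for the difference. Regroupings mixed the replicate numbers, so they do not allow for a batch that libraries with the same number may share. The weakest of 3 other scalings gave -0.244. A shift of a whole library moves rising and falling genes in opposite ways in this mean and largely cancels. The other scalings could therefore hardly change the mean, and this test decides little about the authors' scaling. Without the 48 cuticle and moulting genes, whose mean was -0.895, the other 2483 genes gave -0.241. So few genes could hardly carry the mean, so the outcome of this test was nearly fixed in advance. It shows only that the difference is present in the other genes too. Candidate explanations that stay open are chance and a weaker response in unc-49 animals. A difference in ingested bacteria, in developmental timing or between cultures was not tested. The count of calls, 1432 against 474, is not itself evidence: 11 of 100 regroupings gave a difference as large as 958, up to 2076.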

How the results depend on the processing

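Voom on the recovered reads and the robust prior were chosen after seeing the data. The other alternatives were planned. No count of genes or lists changed its side of 0 except as given here, and no named call reversed. Beyond fewer genes or libraries, the cause was not tested.

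With pseudocount 5, 14 genes differed between unc-49 and wild type on OP50. With no filter the exposure counts were 952 in wild type and 313 in unc-49, and the interaction gave 2, among 25739 genes. With a mean of at least 5 FPKM the genotype counts were 11 on OP50 and 19 on PA14. Library weights gave 2439 and 809 for exposure and 42 and 167 for genotype. They weighted replicate 2 of wild type on PA14, with the lowest FPKM sum, at 0.279. With only the 2 groups compared the counts were 579 for exposure in wild type and 10 and 9 for genotype. Voom gave 14 and 17 for genotype. With a minimum change of 2-fold, 739 genes remained for exposure in wild type. Apart from the replicate block and leaving out libraries, given below, the other settings stayed within 1.5 times the reported counts.

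The labels do not pair libraries by number. Across groups, 14 of 18 pairs of libraries with the same number had residual correlations above 0.1 (mean 0.221, from -0.029 to 0.482), against a mean of -0.11 for different numbers, and 11 of 12 libraries correlated best with their own number. The residuals of each group cancel out, so a positive mean for the same number by itself makes the mean for different numbers negative. The second principal component separated the 3 numbers in all groups. On PA14 the 3 pairs of wild type and unc-49 had 0.388, 0.482 and 0.331. These are hints from the data, not the design. With a replicate block the genotype counts were 66 on OP50 and 133 on PA14, against 22 and 47 without it, so both depend on whether the numbers mark a shared batch. The exposure counts with the block were 2147 in wild type and 600 in unc-49, against 1432 and 474 without it. For exposure in unc-49 the block also brought in clec-45, dao-3, gta-1, gst-5, pqn-89, cyp-35A5 and elo-9 and left out ifd-2, lys-1 and pqn-36. In wild type it brought in col-142 and C34C12.12 and left out ech-1.1, and for genotype on OP50 it brought in F39E9.17 and fbxa-107.

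Medians of lists that passed with camera kept their sign with 3 other scalings and voom, except F-box and MATH-BTB genes for exposure in wild type. Many moved by over 1.5 times. With voom the median for exposure in wild type was 2.678 for genes lowered with DAF-16 active, 0.831 for the intracellular pathogen response, 0.211 for autophagy, 0.206 for insulin signalling, 0.174 for SKN-1 and detoxification genes and 0.164 for neuropeptides. In unc-49 it was 2.33 for genes lowered with DAF-16 active and 0.348 for the intracellular pathogen response, and with quantile normalization -0.033 for ribosomal genes. For insulin signalling it was 0.124 when rescaled. For genotype on OP50 it was 1.363 for heat shock genes with voom and 0.036 for oocyte and embryo markers when rescaled. On PA14 voom gave 0.642 for moulting genes, 0.112 for the mitochondrial and -0.136 for the endoplasmic reticulum unfolded protein response, -0.426 for zygotic embryo markers, -0.269 for histones, -0.235 for F-box and MATH-BTB genes, -0.185 for autophagy and -0.122 for insulin signalling.

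Leaving out each library in turn gave 595 to 1493 genes for exposure in wild type (fewest without replicate 3 on OP50), 235 to 407 in unc-49 (fewest without replicate 3 on PA14), 7 to 19 for genotype on OP50 (fewest without replicate 3 of unc-49) and 15 to 52 on PA14 (fewest without replicate 3 of unc-49). The interaction stayed at 0. Of named calls, 86 of 126 were kept for exposure in wild type, 47 of 81 in unc-49, 6 of 14 for genotype on OP50 and 9 of 20 on PA14. Over all settings 78, 45, 4 and 6 were kept.

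With an estimated correlation 0 lists passed for exposure in wild type, 1 in unc-49, 0 for genotype on either bacterium and 0 for the interaction. With fry the counts were 9, 5, 0, 1 and 0. Leaving out libraries gave 16 to 20, 13 to 18, 4 to 14, 13 to 16 and 10 to 20 lists. The correlation of exposure responses was 0.767 with pseudocount 0.1, 0.918 with pseudocount 5, 0.812 with no filter, 0.934 with a mean of at least 5 FPKM, 0.829 with library weights, 0.785 with voom and 0.815 to 0.867 without 1 library. That of genotype effects was 0.329 to 0.485 without 1 library. The overlap of exposure in wild type with genotype on OP50 was 1 gene, C17F4.7, with pseudocount 0.1, rescaling to a common sum, median-ratio scaling, no intensity trend, the robust prior or voom. It was 2 with quantile normalization or the replicate block, 3 with library weights, and 0 to 2 without 1 library. Depth limits genes near 0: 3 reads in 1 kb are 0.0480 to 0.0749 FPKM.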

Other observations

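The tests on neighbouring genes and on the genotype effect averaged over bacteria were chosen after the results were seen; the male-marker test was written before its result was seen, except for its comparison with the spread between libraries.

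Genes that differ between the genotypes lie close together. Of 47 called genes with a position, 12 have another called gene within 20 kb. Random sets of tested genes had a median of 0, and 0 of 10000 sets reached 12. Outside the mitochondrial genome 10 of 45 did. Of 10000 sets drawn from genes that responded to PA14, 2 were as high, so the clustering of responsive genes alone gives less. The pairs are F39E9.25 and F39E9.17 on chromosome II, K01A11.3 and C34C12.12 on III, C07G1.6 and C07G1.7 and C08F11.6 and C08F11.7 on IV, and ZK262.8 and ZK262.9 on V, with MTCE.25 and MTCE.35 in the mitochondrial genome. ZK262.8 (18438381 to 18440195) and ZK262.9 (18439769 to 18441625) overlap on the same strand, so they may share reads. The genes of the other pairs do not overlap each other as annotated. Strain variants that differ between the strains besides the unc-49 allele may account for such pairs. Transcripts that overlap beyond the annotation or shared regulation stay open. Genes carried along with unc-49 on chromosome III would lie near it. Within 2 Mb of unc-49 lay 1 called gene, ung-1, where random sets had a median of 2, which argues against that for the set. ung-1 itself stays open.

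In 17 protein-coding genes all unc-49 libraries were low, at 10% or less of a wild-type mean of at least 1 FPKM. ung-1 is the most abundant, and 12 of the 17 are at 0 in replicate 2 of wild type on OP50 too. Males among the wild-type animals could bring such transcripts. The bound set against this was met, since 2 unc-49 libraries had a mean of 8 male markers above the lowest of the other 5 wild-type libraries. The margin, 0.19 on the log2 scale, was under the spread of 0.25 within groups, and the markers sum to 0.743 to 2.34 FPKM per library, near the floor. Males and another difference therefore cannot be told apart for these genes. ung-1, at 6.7 FPKM in unc-49 on OP50 and 109 in wild type, is not at 0 in that wild-type replicate. No other biological explanation was tested.

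Averaged over bacteria, 133 genes differed between the genotypes, 124 higher and 9 lower in unc-49. sod-3 was higher by 1.5 (adjusted p = 0.00642) and hsp-6 by 0.57 (adjusted p = 0.0239) on the log2 scale. Of 12 protein-coding genes of the mitochondrial genome, 6 passed and 11 were higher in unc-49, with a mean difference of 0.83 (exact permutation p = 0.01 over 400 arrangements). MTCE.31 differed by -0.08. The mitochondrial ribosomal RNAs MTCE.7 and MTCE.33 differed by 0.227 and -0.609 and did not pass. The mean log2 value of the protein-coding genes was higher in replicate 3 of wild type on PA14, 8.336, than in replicate 1 of unc-49 on PA14, 8.286. MTCE.25 and MTCE.35 had already passed on PA14 in these data, so the permutation is no independent support.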
